A study of Mus musculus with 6 samples.

How the data were processed

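Messenger RNA was sequenced from mouse bone marrow LSK cells, the lineage-negative, Sca1-positive, Kit-positive fraction that holds the blood stem cells and early progenitors. Per the labels' protocols, cells of C57BL/6 mice were sorted and exposed to a retrovirus on coated plates. They were then cultured for 2 days with IL-3 and IL-6 at 10 ng/mL and stem cell factor and Flt3 ligand at 50 ng/mL. RNA was taken from the cells that sorted positive for GFP, so cells that did not carry the virus were removed before RNA extraction. The 6 libraries fall into 2 groups of 3. MIG is the empty GFP vector and MIG-Hhex is the same vector with Hhex. Groups were taken from the vector label of each sample, and the replicate names WT3, WT691 and WT703 from the sample titles, which add a letter for the vector. The labels place both libraries of replicate WT3 on flow cell C3RJFACXX and the 4 libraries of replicates WT691 and WT703 on flow cell C5LWPANXX.

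The deposited table holds 1 row per Entrez gene, 12161 in all, and a log2 value per library. Per the submitters' processing notes, Subread, featureCounts, limma and edgeR were used with the mouse genome build mm10. Versions and the order of the steps are not given in the sources used here. The normalization of the deposited log2 values is also not given there. The values themselves run from below 0 to about 13 and look like a log2 expression value per unit of gene length. Library medians lie close together, between 3.56 and 3.60, while the SD across genes runs from 2.58 to 2.69, so the distributions are alike but not equal. Between 27 and 91 genes per pair of libraries share an exactly equal value. Read counts cannot be recovered from such values, so the depth of each library is unknown. No counting interval can be given, and no count model was run. Whether the normalization removed an overall rise or fall of RNA per cell cannot be told, and the log2 value of a weakly expressed gene depends on the offset added before the log was taken. Fold changes of genes with values below 0 are therefore the least certain in size. In 60 rows the table gives no symbol. No per-sample column was left unused.

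The deposited log2 values were compared with limma 3.58.1 in R 4.3.3. Each gene was fitted with a term for the flow cell and a term for the vector, followed by eBayes with a mean-variance trend. P-values were two-sided and adjusted over all genes by the Benjamini-Hochberg method, with a threshold of 0.05. A gene was to be kept if its value lay above the library's minimum in at least 3 of the 6 libraries; this removed 0 genes. Fold changes are MIG-Hhex minus MIG on the log2 scale, each with the standard error of the fit. Genes were matched by Entrez ID to the RefSeq genes of GRCm38.p6, the same build as mm10, and 12052 matched; coordinates are from that table. Gene and sample groups, the gene lists, the tests and most alternatives were fixed before the data were examined.

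In all, 31 gene lists were fixed for cell types, pathways and complexes, and 30 had at least 3 measured members and were tested. The remaining list, mitochondrially encoded genes, had 0 measured members. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and the Benjamini-Hochberg adjustment over the 30 lists. Camera asks whether the members' changes differ from those of all other genes. Beside it stand camera with the correlation estimated from the residuals, and fry, which asks whether a list's members move on balance in a common direction. Of the 8 lists called at the preset correlation, 0 were called with an estimated correlation (limma camera, adjusted p = 0.826 for each) and 0 by fry. The mixed test of fry, which counts changes in either direction, called 25 of the 30 lists. With 6 libraries and 3 residual degrees of freedom the estimate itself is imprecise. Camera with an estimated correlation also takes its p from those 3 degrees of freedom, which leaves it little power. Its smallest unadjusted p was 0.0743, for T and NK cell genes, and the adjustment gave most lists the same 0.826. Its lack of calls therefore does not decide whether a called list changed.

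Genes named in the text follow a rule fixed beforehand. It takes Hhex, Cdkn2a and Cdkn2b, then the 12 largest rises and 12 largest falls among genes past the threshold with the same sign in all 3 pairs. It adds up to 4 members with the smallest p in the direction of each called list and up to 2 members of every other list. Clone names and unnamed predicted genes were passed over. Cdkn2a and Cdkn2b were not analysed here. Some genes that the rule names are not reported here. Other list members named in the report were chosen after their values were seen, and the sentences that hold them say so.

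Whether equal replicate numbers pair the libraries was checked before fits were compared. Deviations from the group means were correlated between the groups. The correlation was 0.742 for replicate WT3, 0.585 for replicate WT691 and 0.656 for replicate WT703, while the highest value between different numbers was 0.166. The titles' numbers therefore pair the libraries. The series' design text calls the samples biological replicates, but no label names an animal or says what a number stands for. The main fit has a flow cell term but no replicate term, so it does not use this pairing in full. Its error holds the level difference between replicates WT691 and WT703 as well as differences between pairs in the vector's effect. A fit with the replicate number as a block was an alternative.

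Other alternatives were leaving out the flow cell term, dropping the filter, and a filter on the mean at the 25th percentile. Quantile normalization, median centring, eBayes without trend, robust eBayes, and leaving out each library or each replicate number completed the planned ones. Leaving out either library of replicate WT3, or both, gives the same fold changes, because the flow cell term absorbs a single library left on its flow cell. Those left-out runs are therefore not separate checks. Pseudocounts and count models do not apply to these values. After the data were seen, a removal of the GC trend was added, with and without the block. For this, each library's deviation from the gene mean was smoothed against transcript GC content, from GENCODE vM21 transcripts of 11740 genes (96.5%), and the smooth was subtracted.

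The fit was tested on simulated data for this comparison, with the 12161 real genes and 50 genes changed at each of several known sizes. Normal noise was drawn independently for each gene and library, with the spread that eBayes estimated for the gene. At a log2 change of 0.5, 72% were called in the right direction, at 1, 82%, at 2, 94% and at 3, 96%. Among 11939 unchanged genes, 10 were called. A gene list shifted by 0.5 was called by camera and 0 other lists were. Because the simulated genes and libraries were independent, these counts cannot show how often false calls arise where genes vary together or libraries are paired. The test of adjacent genes was tried on simulated calls over the 12048 genes placed on chromosomes. Scattered calls gave a permutation p of 0.286, and 100 planted pairs gave 0.000999, the smallest that 1000 shuffles can give. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.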

Results

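Gene expression was measured by mRNA sequencing in 6 libraries of mouse LSK cells, the bone marrow fraction that contains blood stem cells and early progenitors. Of these, 3 libraries came from cells carrying the empty retroviral vector MIG and 3 from cells carrying MIG-Hhex. Hhex is a homeobox transcription factor of the early blood and endothelial lineages. All cells were cultured for 2 days after transduction and sorted for the vector's GFP. The comparison asks which genes differ between cells with added Hhex and cells with the vector alone. Values for 12161 genes were available on a log2 scale, with library medians between 3.56 and 3.60. The sequencing depth behind them is unknown.

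Hhex itself was higher in every MIG-Hhex library than in any MIG library. Its log2 value was 5.12 ± 0.07 (SD, n = 3) with MIG and 8.67 ± 0.93 (SD, n = 3) with MIG-Hhex, an 11.7-fold rise (log2 fold change 3.55, SE 0.32, limma adjusted p = 0.00189). The rise was 2.43 in the pair of replicate WT3, 4.29 in the pair of replicate WT691 and 3.93 in the pair of replicate WT703. Hhex has Entrez ID 15242 and lies on chromosome 19 from 37434841 to 37440731 in GRCm38. Reads from the vector's Hhex and from the cell's own gene were not separated, so the values hold both.

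**Figure D1:**
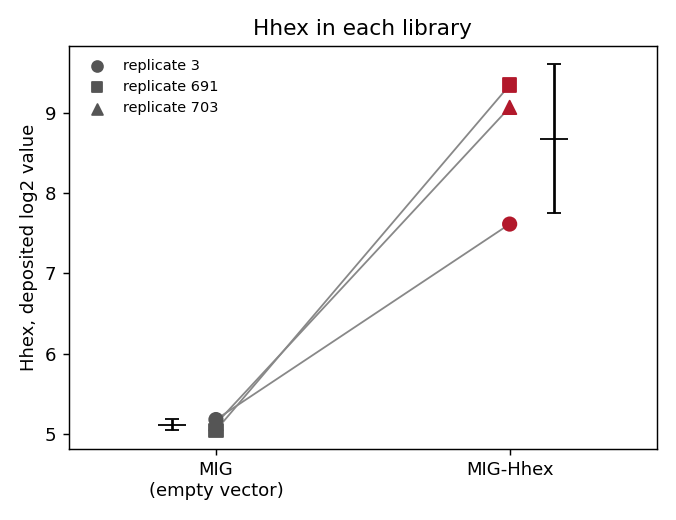
Deposited log2 value of Hhex in each of the 6 libraries, by group, with lines joining libraries of the same replicate number and black bars giving the group mean ± SD (n = 3). MIG libraries lie between 5.05 and 5.18 and MIG-Hhex libraries between 7.61 and 9.34.

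With MIG-Hhex, 1148 genes were higher and 1036 lower, together 18.0% of the genes measured (limma, adjusted p under the threshold). The largest rise was that of Alox15, the 12/15-lipoxygenase of macrophages and eosinophils, by 4.80 on the log2 scale (SE 0.52, 27.9-fold, limma adjusted p = 0.00301). Apoc2, the apolipoprotein that activates lipoprotein lipase, rose 23.2-fold (log2 4.54, SE 0.18). Slc6a4, the serotonin transporter, rose 20.6-fold and Dmpk, the myotonic dystrophy protein kinase, 20.4-fold. The remaining genes of the 12 largest rises were Hap1, Serpina11, Tspan18, Chil1, Dapk2, Tspan15, Wnk2 and Hba-a1. Among them Chil1 is a chitinase-like protein, Dapk2 a death-associated kinase, and Tspan15 and Tspan18 are tetraspanins. Hba-a1 encodes alpha globin and has a near-identical copy, Hba-a2; whether the 2 share reads was not tested, so its value is uncertain. The lowest MIG means in this group were −5.46 for Tspan18 and −5.15 for Hap1, and the highest was 0.80 for Chil1. The other 11 lay below 0 in each MIG library. Chil1 lay at 3.81 in the MIG library of replicate WT3 and at −0.70 in the other 2, and it rose by 1.64, 5.35 and 4.79 in the 3 pairs. Hap1, Tspan18, Tspan15 and Chil1 missed the threshold in some of 9 runs that left out a library or a replicate number (limma adjusted p up to 0.0865, 0.0998, 0.0838 and 0.0906).

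The largest fall was that of Nebl, the actin-binding protein nebulette, by −4.24 on the log2 scale (SE 0.65, limma adjusted p = 0.0091). Slc28a2, a nucleoside transporter, had the smallest p of the 12 largest falls, at −3.81 (SE 0.13, 14.0-fold lower, limma adjusted p = 0.000232), and its MIG mean was 3.85. Lpxn, the focal adhesion protein leupaxin, fell 14.3-fold from a MIG mean of 3.98. The other 9 of the 12 largest falls were Tmem150b, Mrgpra2b, Nxpe2, Pid1, Htra1, Akr1c18, Lpo, Samd4 and Cd200r3. Of these, Htra1 is a secreted serine protease, Akr1c18 a steroid-metabolizing reductase, Lpo a peroxidase and Cd200r3 a receptor of mast cells and basophils. Lpo starts 2.02 kb beyond the end of Mpo on chromosome 11, and reads running past Mpo could be counted in it. Apart from Slc28a2 and Lpxn, the genes fell to MIG-Hhex means between −5.46 (Lpo) and −3.17 (Mrgpra2b). Lpo, Htra1, Samd4, Cd200r3 and Pid1 had MIG means that were already negative. The size and order of these falls are thus uncertain, since the offset of the log2 values is unknown. Nebl, Nxpe2, Htra1, Lpo and Pid1 missed the threshold in some left-out runs (limma adjusted p up to 0.0681, 0.0635, 0.0592, 0.0629 and 0.0525).

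**Figure D2:**
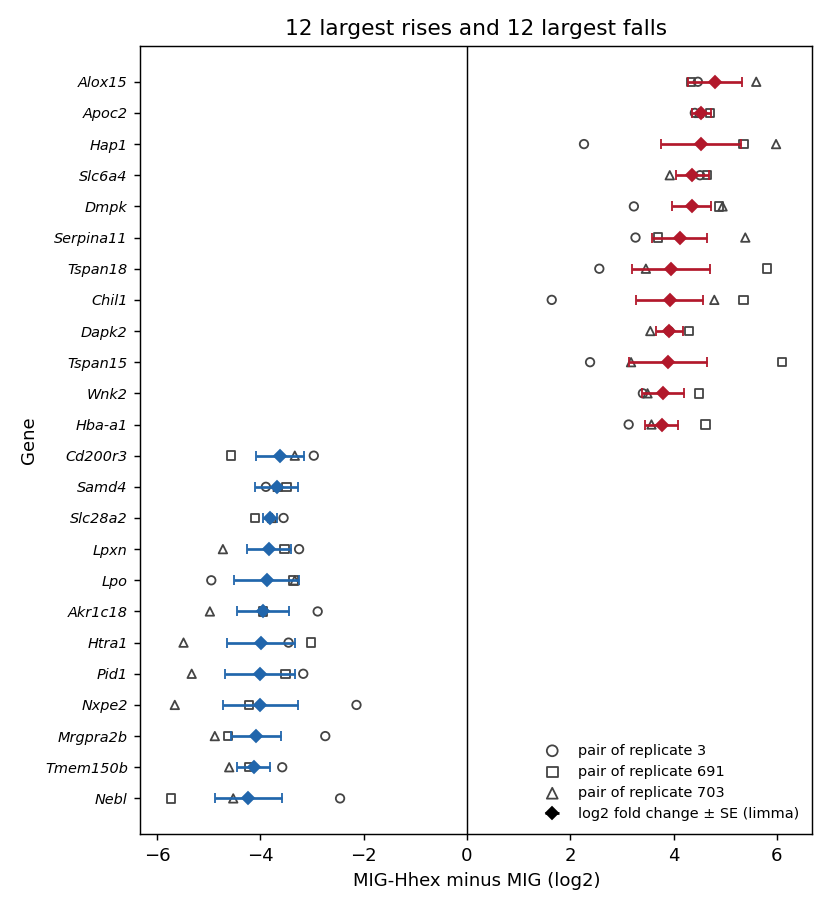
Log2 fold change (MIG-Hhex minus MIG) of the 12 genes with the largest rise and the 12 with the largest fall, as diamonds with the standard error of the limma fit and open symbols for the 3 pairs of libraries. Rises run from 3.77 for Hba-a1 to 4.80 for Alox15, and falls from −3.62 for Cd200r3 to −4.24 for Nebl.

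All 1148 higher and 1036 lower genes had the same sign in the 3 pairs, and 338 and 282 of them changed by at least 1 on the log2 scale. At an unadjusted p under 0.05 there were 4170 genes (limma). Within flow cell C5LWPANXX alone, 698 genes were higher and 519 lower (limma). The other flow cell holds a single pair, in which 97.4% of those 698 were also higher and 94.8% of those 519 also lower, against 46.9% and 52.6% of all genes. Without the flow cell term, 119 genes were higher and 98 lower, and 57 of the 89 named genes that passed the threshold no longer did. Leaving out single libraries or replicate numbers gave 355 to 835 higher and 270 to 634 lower genes, the fewest without replicate WT703. The median transcript GC content was 54.7% for the higher, 48.3% for the lower and 50.4% for the other genes. GC content correlated with the log2 fold change across genes (Spearman rho 0.299; 0.214, 0.289 and 0.283 in the 3 pairs). Whether this trend is technical is open. With it removed, 1064 genes were higher and 981 lower (limma), 937 and 806 of them shared with the counts above.

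The first principal component of the 1000 most variable genes held 48.3% of the variance. MIG libraries lay at −33.3, −21.8 and −23.1 on it, for replicate WT3, replicate WT691 and replicate WT703, and MIG-Hhex libraries at 2.60, 39.2 and 36.3. The second component held 32.9% and set the libraries of replicate WT3, at 22.8 and 38.3, above the other 4, which lay between −28.7 and 0.81.

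Genes of the neutrophil lineage moved in both directions. Of 27 measured neutrophil granule and granulocyte genes, 13 rose, 5 fell and 9 did not pass the test. Cxcr2, the receptor that draws neutrophils to chemokines, rose 4.07-fold (log2 2.03, SE 0.15) and Cebpe, a transcription factor of late granulocyte maturation, 3.19-fold (log2 1.67, SE 0.14). Ngp, a secondary granule protein, rose by 2.08 and Padi4, which citrullinates histones, by 1.18. Chosen after their values were seen, Mmp9 (gelatinase B, 2.97), Camp (cathelicidin, 1.36) and S100a9 (calprotectin subunit, 1.12) rose too. In the other direction, also chosen after their values were seen, Mpo, the myeloperoxidase of primary granules, fell from 10.96 ± 0.39 to 7.84 ± 1.33 (SD, n = 3), an 8.70-fold fall (SE 0.50 on the log2 scale, limma adjusted p = 0.0105). Chil3 fell by 3.29, Mmp8, the neutrophil collagenase, by 1.94, Ms4a3, a marker of granulocyte-monocyte progenitors, by 1.84, and Serpinb1a, an inhibitor of neutrophil elastase, by 1.59. The primary granule proteases Elane, Prtn3 and Ctsg, likewise picked afterwards, had log2 fold changes of −0.14, −0.12 and −0.42 and did not pass (limma adjusted p = 0.615, 0.496 and 0.114). The list was called higher by camera (adjusted p = 0.00726), but not with an estimated correlation (adjusted p = 0.826). For this list and those below, the test with an estimated correlation rests on 3 residual degrees of freedom and has little power. Adjusted over the list alone, 16 genes were higher and 6 lower. The median member stood 0.54 above MIG.

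**Figure D3:**
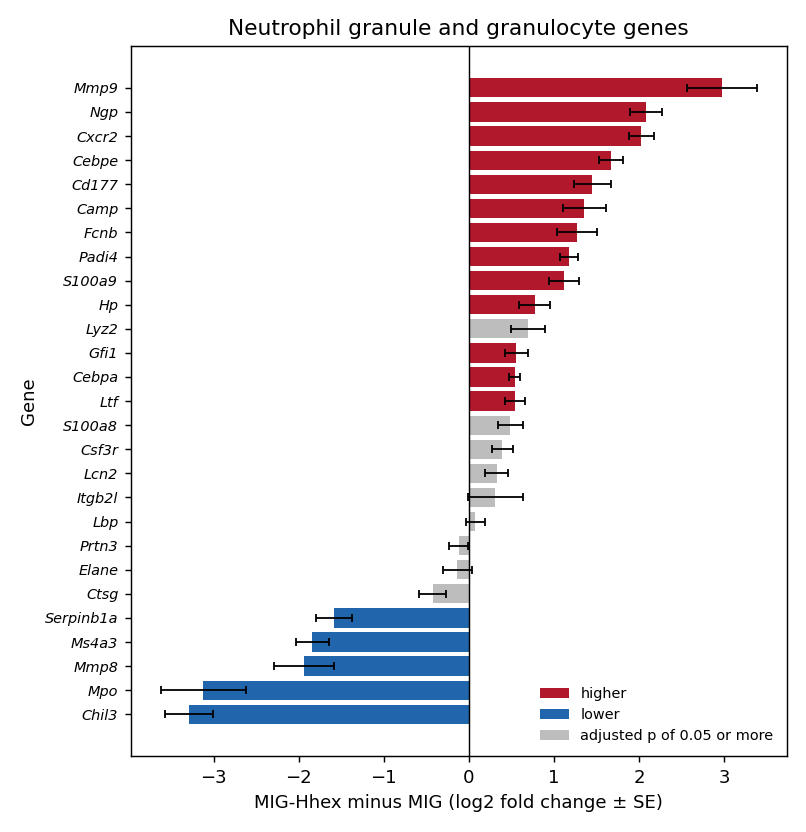
Log2 fold change (MIG-Hhex minus MIG) with its standard error for the 27 measured neutrophil granule and granulocyte genes, coloured by whether the limma adjusted p was under 0.05. The bars run from −3.29 for Chil3 and −3.12 for Mpo to 2.97 for Mmp9.

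Among 34 interferon-stimulated genes measured, 7 rose, 1 fell and 26 did not pass, and 33 had a positive fold change. Rsad2 (viperin, an antiviral enzyme) rose by 1.95, Zbp1 (a sensor of viral nucleic acid) by 1.58, Gbp2 (a guanylate-binding GTPase) by 0.97 and Lgals3bp (a secreted galectin-3 ligand) by 0.68. The list's call by camera (adjusted p = 9.89e-06) was lost with an estimated correlation (adjusted p = 0.826). Adjusted over the list alone, 11 were higher and 1 lower. The list's median difference was 0.28 in the pair of replicate WT3, 0.97 in the pair of replicate WT691 and 0.56 in the pair of replicate WT703. Of the 4 genes, Rsad2, Zbp1 and Gbp2 each lost their call in some of the 9 runs that left out a library or a replicate number (limma adjusted p up to 0.106, 0.121 and 0.0585).

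Of 10 measured MHC class II genes, which present antigen, 6 were higher, 1 lower and 3 not past the test, with a median of 0.97. Ciita, the master regulator of the class, rose 8.60-fold (log2 3.10, SE 0.39) from a MIG mean of −4.12. Cd74, the invariant chain, rose 5.16-fold (log2 2.37, SE 0.31), H2-Eb1 by 2.06 and H2-Aa by 2.12. The single member that fell, chosen after its value was seen, was H2-Oa, which restrains peptide loading, by 0.66. Camera called the list (adjusted p = 0.00726), and with an estimated correlation it did not (adjusted p = 0.826). With p adjusted over the list alone, 7 were higher and 1 lower. The call of H2-Aa was lost in 5 of the 9 left-out runs (limma adjusted p up to 0.10).

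T and NK cell genes gave 7 higher, 0 lower and 3 not past the test among 10 measured of 25 listed. Cd7, a surface protein of T and NK cells and of some progenitors, rose 7.09-fold (log2 2.83, SE 0.36). Zbtb16, the factor PLZF, rose by 1.51, Tcf7, a factor of early T cell commitment, by 1.33, and Id2, an inhibitor of basic helix-loop-helix factors found in many blood cells, by 1.08. Several of these genes are active outside T and NK cells. The list was called higher by camera (adjusted p = 0.00726), not with an estimated correlation (adjusted p = 0.826). It was not called with the stricter filter on the mean (adjusted p = 0.479), nor without replicate WT691 (adjusted p = 0.0564). The call of Zbtb16 was lost without replicate WT703 (limma adjusted p = 0.0528). With p adjusted over the list alone, 7 were higher and 2 lower.

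Of 30 measured genes of stem cells and multipotent progenitors, 0 rose, 4 fell and 26 did not pass, and the median was −0.24. Among those that fell were Meis1, a homeobox factor of stem cells, by 0.79, and Mllt3 and Hoxb4, which maintain them, by 0.57 and 0.49. Kit and Cd34, surface proteins of progenitors chosen after their values were seen, had fold changes of −0.17 and −0.19 and did not pass (limma adjusted p = 0.265 and 0.303). Camera called the list lower (adjusted p = 0.0124), and with an estimated correlation it did not (adjusted p = 0.826). With p adjusted over its members alone, 0 were higher and 4 lower. The call was lost with the filter on the mean (camera adjusted p = 0.119) and without replicate WT3 (camera adjusted p = 0.0556). Leaving out either library of that replicate gives the same estimate and is not a further loss. Meis1 and Mllt3 lost their call in some left-out runs (limma adjusted p up to 0.0584 and 0.179), and Hoxb4 in each of the 9 (up to 0.156).

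Of 22 glycolysis genes measured, 9 rose, 1 fell and 12 did not pass, with a median of 0.22. Slc16a3, which exports lactate, rose 2.93-fold (log2 1.55, SE 0.21) and the glucose transporter Slc2a3 2.52-fold (log2 1.33, SE 0.14). Pfkfb4, which makes an activator of phosphofructokinase, rose by 0.92 and Pfkl, a phosphofructokinase, by 0.49. The single fall, named after its value was seen, was Pgam1 by 0.21. Camera gave an adjusted p of 0.000805, and an adjusted p of 0.826 with an estimated correlation. With p adjusted over the list alone, 12 were higher and 1 lower.

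Among 28 measured genes activated by p53, 7 were higher, 1 lower and 20 not past the test. Btg2, an antiproliferative gene, rose by 1.12, Trp53inp1, a stress-induced regulator of p53, by 0.77, Cdkn1a, the cell cycle inhibitor p21, by 0.68, and Ccng1 (cyclin G1) by 0.32. Plk3, a stress-responsive kinase chosen after its value was seen, was the single member to fall, by 2.43 (5.41-fold). Camera called the list higher (adjusted p = 0.00726), but not with an estimated correlation (adjusted p = 0.826). Adjusted over the list alone, 9 were higher and 1 lower. Each of Btg2, Trp53inp1, Cdkn1a and Ccng1 lost its call in some left-out runs (limma adjusted p up to 0.0583, 0.0545, 0.0853 and 0.079).

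Of 35 measured targets of MYC and genes of ribosome biogenesis, 0 rose, 6 fell and 29 did not pass, while 33 had a negative fold change and the median was −0.18. Rrp9 fell by 0.34, Slc19a1, a folate carrier, by 0.33, and Nolc1, a nucleolar protein, and Srm, spermidine synthase, each by 0.26. The list's camera call (adjusted p = 0.000629) was absent with an estimated correlation (adjusted p = 0.826). With p adjusted over the list alone, 0 were higher and 6 lower. In most of the 9 left-out runs these 4 genes missed the threshold, Srm in all of them (limma adjusted p up to 0.151).

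**Figure D4:**
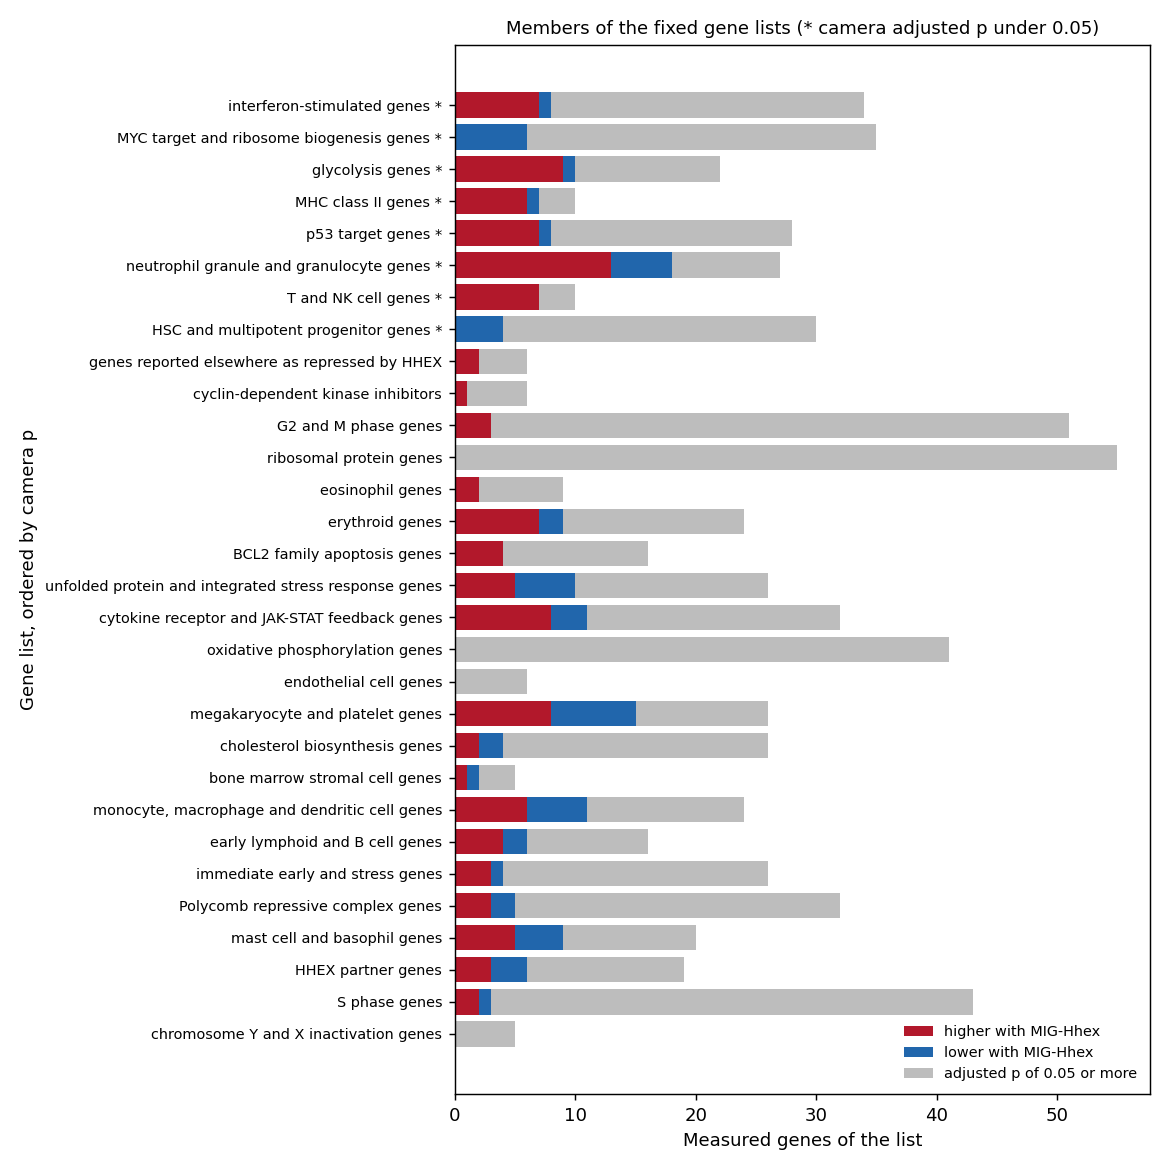
Number of measured genes in each fixed list that were higher, lower or not past the threshold (limma adjusted p of 0.05 or more) with MIG-Hhex, in the order of camera's p; asterisks mark the 8 lists called at the preset correlation, 0 of which were called with an estimated one. Neutrophil granule and granulocyte genes have the most higher members, 13, and megakaryocyte and platelet genes the most lower members, 7.

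The other 22 tested lists were not called by camera, and several held members that moved apart. Of 24 monocyte, macrophage and dendritic cell genes, 6 rose and 5 fell (camera adjusted p = 0.591). Itgax, the dendritic cell integrin CD11c, rose 8.24-fold (log2 3.04, SE 0.22), while Ccr2, the chemokine receptor of classical monocytes, fell 4.12-fold (log2 −2.04, SE 0.17). F13a1, a coagulation factor of monocytes picked after its value was seen, fell by 2.69. Of 20 mast cell and basophil genes, 5 rose and 4 fell (camera adjusted p = 0.706). The proteases Cpa3 and Mcpt8 fell by 2.19 and 1.12. Among 26 megakaryocyte and platelet genes, 8 rose and 7 fell (camera adjusted p = 0.401), with the tetraspanin Cd9 up by 1.46 and the protease inhibitor Serpine2 down by 1.76. Of 24 erythroid genes, 7 rose and 2 fell (camera adjusted p = 0.0762). Hba-a1 rose by 3.77, from a MIG mean of −1.65, and Zfpm1, the GATA1 cofactor FOG1, rose as well (limma adjusted p = 0.00314). The erythroid list was called higher without replicate WT703 (camera adjusted p = 0.0255) or its MIG library alone (0.00985). Of 9 eosinophil genes, 2 rose, Alox15 and the surface lectin Siglecf, the latter by 1.81 (camera adjusted p = 0.0762). Of 16 early lymphoid and B cell genes, 4 rose and 2 fell (camera adjusted p = 0.635). Satb1, a chromatin organizer of early lymphoid cells, fell by 1.04. The list's median of −0.04 and mean of −0.17 lie below 0, while camera's direction is up. In the eosinophil list, the call of Siglecf was lost without replicate WT703 (limma adjusted p = 0.0539), and the list itself was called without replicate WT3 (camera adjusted p = 0.0308) or without the MIG library of replicate WT691 (0.0171).

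Few cell cycle genes passed the test. Of 43 S phase genes, 2 rose and 1 fell, with a median of 0.01 (camera adjusted p = 0.731). Of 51 G2 and M phase genes, 3 rose and 0 fell, with a median of 0.05 (camera adjusted p = 0.0762). The transcription factor E2f2 rose by 0.87, Top2a, a topoisomerase of dividing cells, by 0.34, and Nusap1, a spindle protein, by 0.33, while the deubiquitinase Usp1 fell by 0.18. Top2a, Nusap1 and Usp1 missed the threshold in some left-out runs (limma adjusted p up to 0.0769, 0.0884 and 0.15). The G2 and M phase list was called once replicate WT3 was left out (camera adjusted p = 0.043). Of 6 cyclin-dependent kinase inhibitors, 1 rose, Cdkn1a as above, and Cdkn2d had a fold change of 0.23 (limma adjusted p = 0.0879; with the replicate block 0.035). The list was not called (camera adjusted p = 0.0731), except without replicate WT3 (0.0237) and in the fit without a flow cell term. Among 32 Polycomb repressive complex genes, which keep developmental genes silent, 3 rose and 2 fell (camera adjusted p = 0.676). Cbx2 rose by 0.55 and Cbx6 by 0.32, both chromobox members, and both calls were lost in some left-out runs (limma adjusted p up to 0.0881 and 0.0838).

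Genes reported elsewhere as repressed by HHEX gave 2 higher and 0 lower of 6 measured (camera adjusted p = 0.054, and 0.0204 without replicate WT3). These were the endothelial receptors Flt1, by 0.92, and Eng, by 0.34. Flt1 missed the threshold in each of the 9 left-out runs (limma adjusted p up to 0.134) and Eng in 6 of them (up to 0.138). Of 19 genes for partners of HHEX, 3 rose and 3 fell (camera adjusted p = 0.731). The corepressor genes Tle3 and Tle4 moved apart, Tle3 up by 0.93 (SE 0.07) and Tle4 down by 0.83 (SE 0.09). Chosen after their values were seen, Tle2 rose by 2.89 and Tle1 fell by 0.99.

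Of 16 BCL2 family apoptosis genes, 4 rose and 0 fell (camera adjusted p = 0.156). Bmf, which promotes cell death, rose 6.01-fold (log2 2.59, SE 0.19) and Bbc3, the p53-induced PUMA, by 0.66. Among 26 unfolded protein and integrated stress response genes, 5 rose and 5 fell (camera adjusted p = 0.189). Ddit4, an inhibitor of mTORC1 induced by stress, rose by 1.39 and Asns, asparagine synthetase, fell by 0.40. Of 32 cytokine receptor and JAK-STAT feedback genes, 8 rose and 3 fell (camera adjusted p = 0.189). The receptor Il6ra rose by 0.96 and Spry2, a brake on growth factor signalling, fell by 1.20. Among 26 immediate early and stress genes, 3 rose and 1 fell (camera adjusted p = 0.635), with the nuclear receptor Nr4a1 up by 1.21 and Jun down by 0.87. In 26 cholesterol biosynthesis genes, 2 rose and 2 fell (camera adjusted p = 0.498), and the regulators Insig1 and Srebf2 rose by 0.37 and 0.32. Calls of Bbc3, Ddit4, Insig1 and Srebf2 were lost in some left-out runs (limma adjusted p up to 0.103, 0.072, 0.0591 and 0.0628).

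In 2 large lists 0 genes passed the limma test, where 7 and 0 members, in the order below, had an unadjusted p under 0.05. The first, 41 oxidative phosphorylation genes, had a median of 0.07 (camera adjusted p = 0.249). Its members Atp5a1 and Sdhb had fold changes of 0.26 and 0.21 (limma adjusted p = 0.0542 and 0.0558; with the replicate block 0.0253 and 0.042). The second, 55 ribosomal protein genes, had a median of 0.11 (camera adjusted p = 0.0762), and Rplp0 and Rpl24 had fold changes of 0.25 and −0.25 (limma adjusted p = 0.157 and 0.164). With the replicate block the ribosomal protein list was called higher (camera adjusted p = 0.0322), as it was without replicate WT3 (0.00422) or the MIG library of replicate WT703 (0.00334).

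Markers of other cell types that marrow could contribute were few. Of 14 endothelial cell genes 6 were measured, and 0 rose or fell (limma, with 0 under an unadjusted p of 0.05; camera adjusted p = 0.249); Tie1 and Plvap had fold changes of 0.34 and 0.68 (limma adjusted p = 0.226 and 0.253). Of 18 bone marrow stromal genes 5 were measured, and 1 rose and 1 fell (camera adjusted p = 0.524). These were Pdgfrb, a growth factor receptor, up by 1.40, and Fn1, fibronectin, down by 2.36. The list's median, 0.91, and mean, −0.18, differed in sign, and camera's direction was up. Xist and the Y-linked gene Kdm5d, which follow the sex of the mice, had fold changes of −1.21 and −0.86 (limma adjusted p = 0.834 and 0.867). Both libraries of replicate WT703 were low for Xist, at −4.63 and −7.55, and the other 4 libraries lay between 2.57 and 4.73. Kdm5d went the other way, at 2.90 and 2.81 in replicate WT703 and between −7.15 and −4.66 in the other 4. So did the Y-linked gene Ddx3y, at 4.71 and 4.72 against −6.91 to −4.43. Replicate WT703 thus has the values of male cells and replicates WT3 and WT691 those of female cells. Both vectors share this difference, and the fold changes average over it. The list of 5 sex chromosome genes was not called (camera adjusted p = 0.959), except without replicate WT703 (0.032).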

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

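The GC correction was chosen after the data were seen; every other setting was planned. Of the 8 gene lists called by camera, 6 kept call and direction under each setting at the preset correlation in which lists were tested (the 2 eBayes settings do not enter camera): interferon-stimulated, MYC and ribosome biogenesis, glycolysis, MHC class II, p53 target and neutrophil genes. With an estimated correlation 0 lists were called (limma camera, adjusted p = 0.826 for each of the 8). The estimate and the 3 residual degrees of freedom behind that test both widen it, and their parts were not separated. For the T and NK list the estimate was only 0.0538, yet the unadjusted camera p went from 0.00169 to 0.0743. The HSC list was lost with the filter at the 25th percentile (median −0.17, camera adjusted p = 0.119) and without replicate WT3 (0.0556), and over the alternatives at the preset correlation its p ran from 0.00109 to the filter's value. The T and NK list was lost with that filter (median 0.43, adjusted p = 0.479, where fewer of its genes are tested), without replicate WT691 (0.0564) and with the GC trend removed under the replicate block (median 1.28, 0.062), its lowest p being 0.00388. Over the runs that left out a library or replicate number, the median of the HSC list ran from −0.28 to −0.17 and of the T and NK list from 1.29 to 1.39. Hhex rose in every setting, by 3.18 to 4.11 in the left-out runs. The replicate block gave 1506 genes higher and 1473 lower, among them all 1148 and 1036 genes above, so both counts stayed within 1.5 times. No flow cell term gave 119 and 98, all shared; then the spread between flow cells enters the error. Without the eBayes trend 638 genes were lower; the cause was not tested. The left-out runs gave 355 to 835 higher and 270 to 634 lower genes, from fewer samples. With the GC trend removed 1064 were higher (937 shared) and 981 lower (806 shared). Of the 89 called named genes, 86 kept their call after GC removal and 51 in each left-out run; 0 of them reversed in any setting that kept them (the filter at the 25th percentile kept 54).

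Lists not called above were called in some settings (medians; camera adjusted p): without a flow cell term erythroid (0.14; 0.0352), eosinophil (1.67; 0.0115), cyclin-dependent kinase inhibitors (0.25; 0.0339) and HHEX-repressed (0.35; 0.0143), the last also with median centring (0.35; 0.0458); with the block ribosomal protein (0.11; 0.0322); with the GC trend removed G2 and M phase (0.10; 0.00505). The cause was not tested. In left-out runs their medians ran from 0.0715 to 0.53 (erythroid), 0.52 to 2.02 (eosinophil), 0.18 to 0.29 (kinase inhibitors), 0.30 to 0.44 (HHEX-repressed), −0.0473 to 0.20 (ribosomal protein) and 0.0363 to 0.0579 (G2 and M phase). The direction of a list is that of camera, which compares it with all other genes, so it can reverse while the printed median keeps its sign. Directions that reversed belong to values called neither in the report nor in the fit where they reversed, and the cause was not tested: with the filter monocyte (−0.11) and mast cell lists (−0.12); with the GC trend removed immediate early (0.00308) and HHEX partner lists (0.0285), and with the block added the same 2 lists at the same medians (0.00308; 0.0285) and early lymphoid (−0.0788). In left-out runs S phase ran from −0.0207 to 0.0321, oxidative phosphorylation from −0.0211 to 0.12, immediate early from −0.0590 to 0.17, HHEX partner from −0.0212 to 0.0470, early lymphoid from −0.0942 to 0.0591, and the sex chromosome list from −3.21 to 1.94, with Xist from −4.50 to 2.32 and Kdm5d from −3.75 to 1.94. Depth is unknown, so what it limits cannot be given.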

Other observations

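The families in this part, the tests on replicate WT3, the tests of shared reads, of granulocyte share and of primary granule genes were chosen after the result was seen. Ms4a genes, membrane proteins of myeloid and mast cells, went down as a family: of 10 measured, 9 were lower and 0 higher, with a median of −1.97 (limma). Ms4a7 fell by 3.45, Ms4a4b by 2.90, Ms4a6d by 2.22 and Ms4a3 by 1.84. All 3 measured CD200 receptor genes were lower, and of 9 annexins 4 were lower (Anxa1 by 1.96, Anxa3 by 1.87) and 1 higher (Anxa4 by 0.53). Of 4 chitinase-like genes, Chil1 rose by 3.93 while Chil3 and Chil4 fell by 3.29 and 2.96. Outside these families, among many other falls and picked after their values were seen, were those of Met, a growth factor receptor (−3.18), the cytokine Il6 (−2.81), Dntt, the lymphoid DNA polymerase (−2.80), and Pparg, a nuclear receptor of lipid metabolism (−2.71).

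Members of other families went up. Of 4 lipoxygenases 3 were higher, Alox15 by 4.80, Alox12e by 3.57 and Alox5 by 1.01, and the apolipoproteins Apoe and Apoc2 rose by 3.59 and 4.54. Of 3 C1q complement chains, C1qb and C1qc rose by 2.37 and 2.11 (limma adjusted p = 0.0481 and 0.0471) and C1qa did not pass (2.88, limma adjusted p = 0.0595), while the fixed list of monocyte, macrophage and dendritic cell genes was not called (camera adjusted p = 0.591). Of 5 stefin A genes, protease inhibitors of neutrophils, 4 were higher with a median of 2.98, though whether near-identical copies share reads was not tested. Of 15 tetraspanins 6 were higher and 1 lower, and of 8 S100 genes 3 were higher and 0 lower. These counts per family were equal under quantile normalization and median centring.

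Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, called 2184 genes, and the highest of the other splits called 0 with the same limma fit. With 10 splits a share under 0.05 is out of reach. The real split parts all 3 pairs of equal replicate number, as do 3 of the others. Each split other than the real one mixes MIG and MIG-Hhex libraries in both groups, so the vector's effect enters its error. The 0 calls there thus do not show how often false calls arise.

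Changes were smaller in the pair of replicate WT3. The 500 genes that rose most in the pair of replicate WT691 had a median difference of 0.99 in the pair of replicate WT3 and 1.46 in the pair of replicate WT703. If untransduced cells mixed into the MIG-Hhex library accounted for its smaller rise of Hhex, the transduced share would be 26.9% and would bound a fall at −0.45, yet 112 genes lower by 2 or more in the other flow cell had a median of −1.66, which argues against that share. A narrower range of values is argued against as well, since the SD there was 2.67 beside at most 2.60 in the other flow cell. A smaller admixture that the GFP sort left (those genes would need a transduced share of 80.9%) and, as a hypothesis, the smaller rise of Hhex (2.43) cannot be told apart from each other or from the flow cell, which holds this pair alone.

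Neighbouring genes changed together. Of 12028 adjacent pairs, 410 moved in the same direction, against a mean of 196 and a maximum of 240 in shuffles of the calls. The permutation p was 0.0001, the smallest that 10000 shuffles can give. Mpo, Lpo and Bzrap1 fell side by side on chromosome 11, and Apoe and Apoc2 rose on chromosome 7. Each of these adjacent pairs lies less than 10 kb apart or shares a family name, so the stricter count below leaves it out. Shared reads are argued against as the whole cause, because pairs without a common family name and at least 10 kb apart gave 225 against 108 (permutation p = 0.0001). A family name was judged by the first letters of the symbols. Stefin A neighbours with unlike symbols, such as Stfa1 and BC100530, therefore stay in that count. GC content is argued against as the whole cause too, because shuffles among genes of like GC gave 222 (permutation p = 0.0001). With the GC trend removed from the values, 310 pairs moved in the same direction against a shuffled mean of 175 (permutation p = 0.0001). These are fewer pairs than the 410, so a part that goes with GC content is not excluded. As to chance placement along the chromosomes, the first shuffles argue against it. Regulation of neighbourhoods by added Hhex may underlie the pattern; that is a hypothesis, and no test here separates it from neighbours that belong to the same cell states.

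Mpo, Chil3 and Ms4a3 fell while other granule genes rose. A smaller share of granulocyte-lineage cells, with their mix unchanged, would lower the list alike, but 13 members rose beside 5 that fell. That count restates the pattern that prompted it, so it is no separate test. It cannot speak to a changed mix of cells within the lineage. A lowered ceiling of the values is argued against, since the 50 highest genes of MIG had a median change of 0.0414 beside −3.12 for Mpo. Loss of the primary granule genes as 1 set is argued against by the median of Elane, Prtn3 and Ctsg, −0.14. These 3 genes were picked after their values were seen, so the argument covers them alone. A shift between maturation stages may remain, as an untested hypothesis: Cebpe, Cxcr2 and Mmp9 of later stages rose, but Mmp8, also of later granules, fell by 1.94, and the early genes Elane, Prtn3 and Ctsg did not pass the test.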
